A study of Mus musculus with 16 samples.

How the data were processed

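Total RNA of mouse two-cell embryos was measured on 16 one-colour oligonucleotide arrays, 4 for each of the groups BBB, BCB, BBB with α-amanitin and BCB with α-amanitin (spelled α-amantin in the labels). Per the labels, RNA was extracted with a Picopure kit and labelled with biotin by an ENZO kit. The deposited values are given as intensity on a linear scale with 1 decimal, for 45037 probe sets of transcripts and 64 control probe sets. Per array, the mean of the values without the highest and lowest 2% is about the same on all arrays, so the authors scaled each array, and array percentiles differ, so the values were not quantile normalized. The software and the scaling method are not given in the sources used here. No pair of arrays held identical values, and no sample column was left unused. The labels give no batch and do not say which replicates share a day, and correlations between arrays of the same number gave no sign that the numbers pair the samples.

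Probe sets were matched to genes with the platform annotation of the series. Of the 45037 probe sets that are not controls, 34945 have 1 symbol, 932 have several and 9160 have none; those with several or none were tested but not counted as genes. Symbols were updated through Entrez identifiers for 59 symbols, with 34741 probe sets matched. Values were taken as log2(value + 16). A probe set was tested where it lay at or above its array's 40th percentile on at least 4 of the 16 arrays, which left 31953 probe sets and 15257 genes and removed 13084 probe sets. A gene was read from its tested probe set with the highest mean over all 16 arrays. All 16 arrays entered 1 linear model with a mean per group in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation, an intensity trend and a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested. The 5 contrasts were amanitin against untreated in BBB, the same in BCB, BCB against BBB untreated, BCB against BBB with amanitin, and the interaction, which is the amanitin effect in BCB minus that in BBB. These choices, the gene lists and the rule for naming genes were fixed before the data were examined.

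The amanitin effects of both kinds were compared by counting shared genes beside the number expected of independent lists. Classes of genes lowered, raised or neither by amanitin were taken from 2 BBB arrays and the difference between kinds from the other 2, with Fisher's exact test (two-sided). In 23 gene lists with at least 5 tested genes, camera with a preset correlation of 0.01 tested whether a list shifted against other genes, adjusted over 115 tests. Members past the threshold were counted over all genes and adjusted over the list alone. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance one way, were run beside it. The lists were two-cell genome activation, early embryonic, oocyte and maternal-effect, nucleolar and ribosome biogenesis, cytosolic ribosomal, translation, spliceosome, RNA polymerase II, proteasome, chaperones, oxidative phosphorylation, mitochondrial ribosomal, glycolysis, cholesterol and fatty acid synthesis, chromatin modifiers, imprinted genes, antigen presentation, interferon response, p53 targets, cell cycle, DNA repair, cumulus and granulosa cell markers, and sperm-carried transcripts.

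Genes were named by a rule: for each contrast the 8 largest rises and 8 largest falls among called genes whose 4 arrays of one group all lay above the 4 of the other (a condition not used for the interaction), and for each list with a call the member with the smallest adjusted p in each direction and the one with the highest mean, at most 30 per contrast. Hspa1a, Hspa1b, Eif1a, Zscan4c, Zp3, Gdf9, Mos, Dnmt1 and Xist were named in every case where tested. Clone names and predicted genes were counted but not named. Names outside the rule were chosen after their values were seen and are marked as such in the comparison or observation that first names them. The order of genes along chromosomes, used for neighbouring genes alone, was taken from RefSeq gene positions.

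Measures per array (the 9 hybridization and 12 poly-A control probe sets, 18S ribosomal RNA, percentiles and 3' to 5' ratios) were compared between groups with exact two-sided permutation tests. The alternatives fixed beforehand were quantile normalization, arrays centred on their medians, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, only the 2 groups compared, the replicate number as a block, no intensity trend, array weights, a minimum change of 2-fold, the list tests named above and leaving out each array in turn. Those chosen after seeing the data were scaling to the hybridization or to the poly-A controls, the position of each array along the axis from untreated to treated as a term, and leaving out BBB arrays 3 and 4. The fit was tested on simulated data with 200 changed probe sets. In the comparison of untreated BCB and BBB it found 18% of changes of 0.5, 74% of 1 and 100% of 2 or 3 on the log2 scale, with 4 false calls among 31753 unchanged probe sets, and with amanitin 22%, 82% and 100%, with 7 false calls. Of 200 random lists in simulated data, 4 had an unadjusted camera p under 0.05. The noise was independent between genes, so this does not test lists of correlated genes. For the simulated probe sets the noise was independent as well. Changes were added at any intensity, also where a fall could not show on an array, so the shares found may be too high. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No value was left out other than by the filter above.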

Results

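Gene expression was measured in mouse two-cell embryos on 16 one-colour arrays, with total RNA labelled with biotin. The embryos were of 2 kinds that differ in the strain of the maternal pronucleus. In BBB embryos the ooplasm and both pronuclei were B6. In BCB embryos the maternal pronucleus was C3H, in B6 ooplasm and beside a B6 paternal pronucleus. Each kind was measured untreated and with α-amanitin, an inhibitor of RNA polymerase II, with 4 arrays in each of the 4 groups. The deposited values were linear intensities for 45037 probe sets of transcripts and 64 control probe sets. The mean intensity per array was 210.2 ± 3.53 (SD, n = 4) in BBB, 210.1 ± 1.40 in BCB, 241 ± 4.24 in BBB with amanitin and 239 ± 2.44 in BCB with amanitin. The 75th percentile of intensity was 118 ± 1.11, 117 ± 2.77, 87.4 ± 2.57 and 89.2 ± 1.37 in the same order. Correlations between arrays, taken across genes, which are not independent replicates, were 0.976 to 0.990 within a group and 0.764 to 0.815 between treated and untreated arrays. The number of arrays limits the precision, with a median standard error of 0.17 on the log2 scale for a difference between 2 groups. The origin of the replicates is not stated, so each p-value measures the spread between these samples. Genes are identified by symbol.

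The first comparison asks which transcripts of BBB embryos depend on transcription by the embryo. With amanitin, Timd2, a cell-surface receptor, fell from an intensity of 2816 ± 372 to 9.2 ± 5.0 (SD, n = 4), a log2 change of −6.82. Calcoco2, an autophagy receptor, fell from 1968 ± 278 to 4.8 ± 2.6 (−6.57), and Ctsc, the lysosomal protease cathepsin C, fell from 2369 ± 203 to 12.6 ± 7.1 (−6.42). Rrs1, a ribosome biogenesis factor, fell from 2796 ± 222 to 18.4 ± 5.7 (−6.36). The size of falls to such low intensities depends on the pseudocount, and that of Timd2 was −8.25 with 1 and −5.29 with 64. In the other direction, Dph6, an enzyme of diphthamide synthesis, rose from 99.5 ± 38.3 to 2460.2 ± 177 (4.48). Mid1, a ubiquitin ligase bound to microtubules, rose from 22.4 ± 6.7 to 632 ± 52.6 (4.09), and Lef1, a transcription factor of the Wnt pathway, rose from 185 ± 54.1 to 1564 ± 95.4 (3.01).

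Among the other genes with the largest falls, Exoc3l2 (−6.47), Ubtfl1 (−6.45), Btbd18 (−6.41) and Riox1 (−6.25) also lost nearly all of their signal. Klk13 (3.23), Cyp2f2 (2.94), Dpys (2.87), Slc25a23 (2.84) and Oas1f (2.83) were among those with the largest rises. In all, 10725 of 15257 genes (70.3%) passed an adjusted p of 0.05 in the limma test, 5667 higher and 5058 lower with amanitin. At least 2-fold changes were 2433 rises and 3338 falls, and at least 8-fold changes were 7 rises and 739 falls. The median log2 change of all genes was 0.11.

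In BCB embryos the same question was asked of an embryo with a C3H maternal pronucleus. Calcoco2 fell from 2508 ± 308 to 5.4 ± 2.7 (−6.88), Timd2 from 3066 ± 286 to 19 ± 7.2 (−6.48), and Exoc3l2 also fell (−6.79). Fgf4, a growth factor of the early embryo, fell from 556 ± 106 to 1.9 ± 1.3 (−4.98), and Dnajb9, a chaperone of the endoplasmic reticulum, fell by 5.32. Mid1 rose from 16.7 ± 5.2 to 703 ± 201 (4.43) and Dph6 from 106 ± 16.4 to 2214 ± 366 (4.19), while Ccni, a cyclin, rose by 2.81 and Casp8, a caspase of apoptosis, by 2.73. Of the 15257 genes, 10963 (71.86%) passed the limma test, 6090 higher and 4873 lower. The median log2 change of all genes was 0.17.

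The arrays carry control probe sets for added transcripts, and these moved with the treatment. Of these, the poly-A controls are the ones added before labelling. Hybridization controls were higher on the treated arrays by 0.56 on the log2 scale in BBB and 0.81 in BCB embryos, and poly-A controls by 1.86 and 1.88. The probe sets for 18S ribosomal RNA were higher by 1.26 and 1.63. Each of these 6 differences had an exact two-sided permutation p of 0.0286 (n = 4 against 4, the smallest that 4 against 4 allows) and an adjusted p of 0.0728. The 3' to 5' ratio of actin, a measure of how complete the labelled RNA is, was lower with amanitin (7.77 to 6.42 in BBB and 8.58 to 6.95 in BCB), with the same p and adjusted p, and that of Gapdh did not pass (exact p 0.6 and 0.314). Because of this, a rise or fall above is relative to the scale of each array. Scaled to the poly-A controls, the median log2 change of all genes was −1.18 in BBB and −1.14 in BCB embryos. Only 154 of the 5667 genes higher in BBB (2.72%) and 126 of the 6090 in BCB (2.07%) then stayed higher, and 3415 and 3656 turned lower, while the falls all stayed. Scaled to the hybridization controls, 3204 of the rises in BBB (56.54%) and 2291 in BCB (37.62%) stayed. The genes with the largest rises, Dph6, Mid1, Klk13, Lef1 and Cyp2f2, kept their direction and their call under every scaling run.

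**Figure D1:**
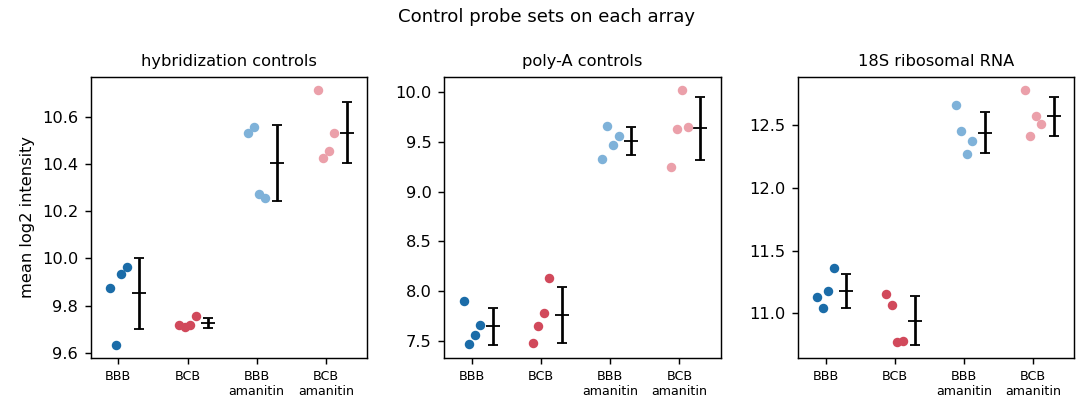
Mean log2 intensity of the hybridization controls, the poly-A controls and the 18S ribosomal RNA probe sets on each array (dots) in the 4 groups, with the group mean ± SD (bars). The treated groups lie above the untreated groups for all 3 measures, for example 9.51 against 7.65 for the poly-A controls in BBB embryos.

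Of the 21 genes tested in a list of two-cell genome activation genes, 20 fell with amanitin in BBB embryos and 20 in BCB embryos. The list's median log2 change was −3.97 in BBB and −3.92 in BCB. Zfp352, a zinc finger gene of the two-cell stage, fell from 4626 ± 579 to 198 ± 21.1 (−4.44), Pramel7 fell from 2719.7 ± 151 to 56.9 ± 26.7 (−5.29), and Dppa4, a chromatin-associated pluripotency factor, also fell (−4.88). The inducible heat shock genes Hspa1a (−4.35 in BBB and −4.40 in BCB) and Hspa1b (−4.14 and −3.39), the translation initiation factor Eif1a (−3.97 and −3.92) and Sp110, a nuclear body protein (−3.14 and −3.08), fell in both kinds. Duxf3 was the 1 member that rose (0.94 in BBB), from 15.6 ± 3.6 to 44.5 ± 6.1, and it turned to −0.22 scaled to the poly-A controls. The probe set of Zscan4c maps to several genes, so Zscan4c was not counted as a gene. Camera's adjusted p for the list was 7.42e-10 in BBB and 4.74e-10 in BCB embryos, against an adjusted p = 0.0518 with an estimated correlation in each. The counts adjusted over the list alone were 1 higher and 20 lower in both kinds. Zfp352, Pramel7, Dppa4 and Duxf3 were named after their values were seen.

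Early embryonic transcripts with roles from cleavage onward fell in 20 of 27 genes in BBB and 19 of 27 in BCB embryos, with medians of −1.17 and −1.12. Klf5, a pluripotency transcription factor, fell from 1049 ± 107 to 39.4 ± 9.7 in BBB (−4.28). The 5 members that rose in BBB were Pou5f1, a regulator of pluripotency (1.254), Gata3 (1.29), Yap1, an effector of the Hippo pathway (0.62), Mycl (0.55) and Klf17 (0.28). Scaled to the poly-A controls all 5 were below 0 (−0.59, −0.24, −1.24, −0.23 and −1.58), and with quantile normalization Klf17 was at −0.31 and Yap1 at −0.01. The list's adjusted p was 0.00119 in BBB and 0.000909 in BCB embryos, and adjusted p = 0.0408 with an estimated correlation in both kinds. In each kind 5 rose and 20 fell when adjusted over the list alone. The 5 risers were named after their values were seen.

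Transcripts for making ribosomes fell together. Of 77 nucleolar and ribosome biogenesis genes, 72 fell in BBB and 73 in BCB embryos, with median log2 changes of −2.39 and −2.46. Nip7, a factor of the large ribosomal subunit, fell from 1599 ± 188 to 55.5 ± 15.4 in BBB (−4.52), the nucleolar chaperone Npm1 fell from 3356 ± 286 to 1275 ± 181 (−1.39), and Nhp2, of the box H/ACA particles, fell by 3.61 in BCB. The 2 members that rose were Nvl (1.15 in BBB) and Pes1 (0.36). Scaled to the poly-A controls they were at −0.47 and −1.46, and Pes1 was at −0.19 scaled to the hybridization controls and at −0.08 with the mean of its probe sets. The list's adjusted p was 7.76e-21 in BBB and 9.52e-22 in BCB embryos, against adjusted p = 0.0518 with an estimated correlation in each. No count changed when adjusted over the list alone. Npm1, Nvl and Pes1 were named after their values were seen.

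Of 44 cytosolic ribosomal protein genes, 41 fell and none rose in BBB embryos, with a median of −2.27, and 40 fell in BCB embryos (−2.41). Rpsa fell from 1549.7 ± 197 to 141 ± 2.5 in BBB (−3.31; −3.45 in BCB). Rps2 (0.13), Rpl39 (0.10) and Rps27l (0.21) did not pass in BBB. In BCB Rps2 (0.27) and Rpl39 (0.39) rose, though the call of Rps2 ended without BCB_amanitin array 1 (adjusted p 0.0515) and that of Rpl39 without BCB_amanitin array 3 (0.0666). Both turned below 0 in BCB scaled to the hybridization controls (−0.54 and −0.29) and to the poly-A controls (−1.60 and −1.19), and Rps2 also with quantile normalization (−0.27). The list's adjusted p was 7.7e-15 in BBB (adjusted p = 0.108 with an estimated correlation) and 1.73e-15 in BCB (0.1). No count changed when adjusted over the list alone. Rps2, Rpl39 and Rps27l were named after their values were seen.

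Translation initiation and elongation factors fell in 30 of 42 genes and rose in 8 in BBB (median −1.05), and fell in 30 and rose in 9 in BCB (−1.08). Eif3c, a subunit of initiation factor eIF3, fell from 3101 ± 256 to 107 ± 18.2 in BBB (−4.67; −4.73 in BCB). The adjusted p was 5.82e-05 and 4.98e-05, against adjusted p = 0.1 with an estimated correlation in BBB and 0.0999 in BCB. Of 86 spliceosome and mRNA processing genes, 59 fell and 15 rose in BBB (−1.70), and 61 fell and 16 rose in BCB (−1.63). The splicing factor Srsf1 fell from 3276 ± 132 to 276 ± 21.1 in BBB (−3.50; −3.41 in BCB). The adjusted p was 1.41e-07 and 2.74e-08, against adjusted p = 0.0627 with an estimated correlation in BBB and 0.0545 in BCB. RNA polymerase II and general transcription factors fell in 39 of 65 genes and rose in 18 in BBB (−0.83), and fell in 41 and rose in 19 in BCB (−0.81). Cdk9, the kinase of the elongation factor P-TEFb, fell from 2319 ± 185 to 158 ± 6.4 in BBB (−3.74; −3.92 in BCB). This list's adjusted p was 0.00357 and 0.00115, against adjusted p = 0.243 with an estimated correlation in BBB and 0.186 in BCB. Adjusted over the list alone, the BBB counts were 9 higher and 30 lower for translation, 16 and 60 for the spliceosome and 18 and 39 for RNA polymerase II. In BCB they were 9 and 31, 16 and 63, and 19 and 41.

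Proteasome subunits fell in 31 of 39 genes in BBB (−1.20) and in 30 in BCB (−1.31), with 6 and 7 rises. Psma6, of the core particle, fell from 2151 ± 467 to 120.4 ± 24.0 in BBB (−3.98; −4.45 in BCB), and the activator subunit Psme3 rose from 777 ± 103 to 2794 ± 302 in BBB (1.83), or −0.01 scaled to the poly-A controls. The adjusted p was 1.99e-05 and 9.88e-06, against adjusted p = 0.135 with an estimated correlation in BBB and 0.119 in BCB. Chaperones and heat shock proteins fell in 30 of 43 genes in BBB (−1.09) and in 31 in BCB (−1.20), with 7 and 9 rises. The chaperonin subunit Cct6a fell from 2224 ± 134 to 67.0 ± 18.7 in BBB (−4.78), and Hspa5, the main Hsp70 of the endoplasmic reticulum, from 4256 ± 227 to 851 ± 161 (−2.32). The adjusted p was 3.92e-05 and 1.49e-05, against adjusted p = 0.07 with an estimated correlation in BBB and 0.0608 in BCB. The BBB counts adjusted over the list alone were 7 higher and 31 lower for the proteasome and 7 and 30 for the chaperones. Psme3 and Hspa5 were named after their values were seen.

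Oxidative phosphorylation genes fell in 49 of 73 in BBB (−0.80) and in 47 in BCB (−0.73), with 12 and 13 rises. Mitochondrial ribosomal proteins fell in 40 of 74 in BBB (−0.45) and 37 in BCB (−0.42), with 14 and 16 rises, and Mrpl51 fell from 1762 ± 114 to 113 ± 24.3 in BBB (−3.80). The adjusted p for oxidative phosphorylation was 0.000274 and 0.00018, against adjusted p = 0.507 with an estimated correlation in BBB and 0.505 in BCB. That for mitochondrial ribosomes was 0.00788 and 0.00975, against adjusted p = 0.505 with an estimated correlation in BBB and 0.507 in BCB, and quantile normalization ended these calls (0.071 and 0.0795). Cell cycle and mitosis genes fell in 42 of 70 in BBB (−0.97) and 43 in BCB (−1.26), with 23 and 20 rises. Cdk1, the kinase that drives entry into mitosis, fell from 2839 ± 105 to 134 ± 28.2 in BBB (−4.27; −4.55 in BCB), and Pcna, the clamp of DNA replication, fell from 3786 ± 212 to 445 ± 70.6 (−3.06). Cdc25b, a phosphatase that activates Cdk1, rose from 403 ± 81.3 to 1429 ± 79.0 in BBB (1.80), or −0.02 scaled to the poly-A controls. The cell cycle list had an adjusted p of 0.00423 in BBB and 0.000646 in BCB, and adjusted p = 0.0408 with an estimated correlation in both. Adjusted over the list alone, the BBB counts were 12 higher and 50 lower for oxidative phosphorylation, 14 and 40 for mitochondrial ribosomes and 23 and 43 for the cell cycle. Pcna and Cdc25b were named after their values were seen.

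Oocyte and maternal-effect transcripts were the 1 list that was higher with amanitin. In BBB embryos 46 of 60 rose and 9 fell, with a median log2 change of 0.75, and in BCB embryos 45 rose and 8 fell (0.69). Zp2, a protein of the zona pellucida, rose from 1039.5 ± 141 to 4215 ± 138 in BBB (2.01). The oocyte growth factors Bmp15 and Gdf9 rose by 1.45 and 0.76, Nlrp5, a maternal-effect protein, by 1.43, Btg4, a factor of maternal mRNA decay, by 1.04, and Mos, a kinase of meiotic arrest, by 0.94 (0.97 in BCB). Obox3, an oocyte homeobox gene, fell in BBB (−5.02) and in BCB (−5.01), and Dppa3, a maternal-effect factor also known as Stella, fell by 1.37 in BBB. Zp3 went from 739 ± 92.3 to 747 ± 66.5 in BBB (0.02) and did not pass the test, nor did Zar1, Fbxo43, Figla and Kit.

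Camera's adjusted p for the oocyte list was 4.98e-05 in BBB and 0.000322 in BCB embryos, against adjusted p = 0.464 with an estimated correlation in BBB and 0.507 in BCB. The member counts were the same adjusted over the list alone. The direction depended on the scale. Scaled to the poly-A controls, the list's median was −1.01 in BBB, with none higher and 51 lower, and −1.08 in BCB, which is 0.17 and 0.06 above the median of all genes. The list's call then ended in both kinds (0.569 and 0.841). Scaled to the hybridization controls, the median was 0.20 in BBB and −0.09 in BCB, where the call ended (0.0731), as it did in BCB with quantile normalization (0.071). Of the named risers, Gdf9 was at −0.19 in BCB with the hybridization controls. With the poly-A controls Gdf9 (−1.09), Bmp15 (−0.40), Nlrp5 (−0.42), Btg4 (−0.81) and Mos (−0.19) were below 0 in BBB, and the call of Zp2 ended (0.425). Zp2, Bmp15, Nlrp5, Btg4, Dppa3, Zar1, Fbxo43, Figla and Kit were named after their values were seen.

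**Figure D2:**
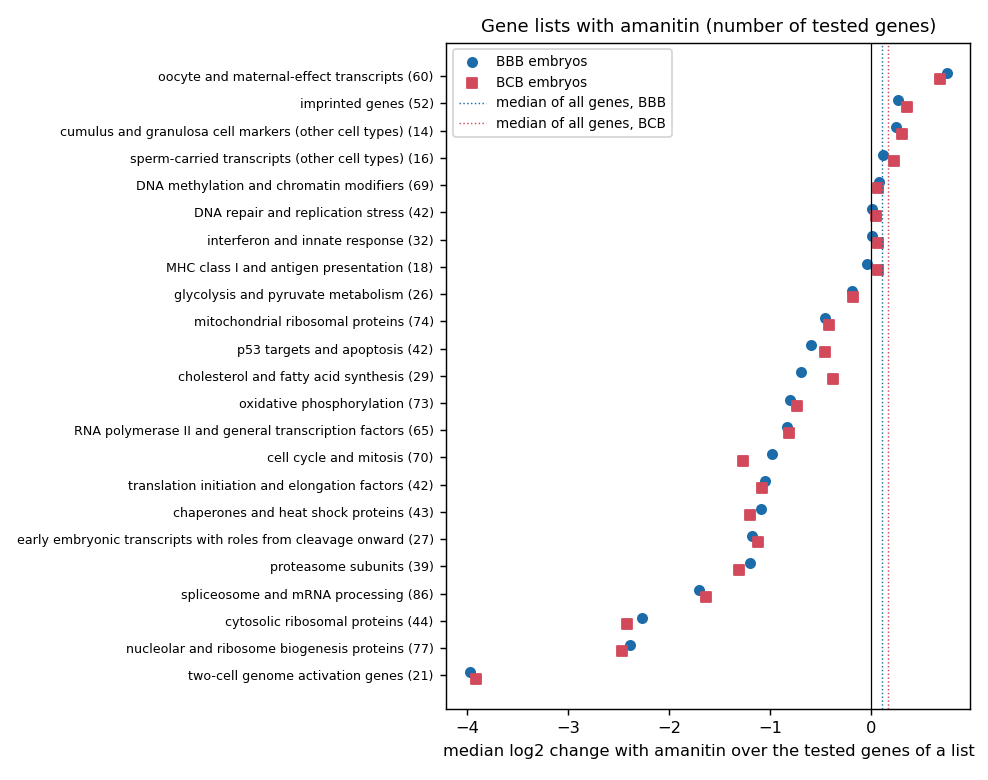
Median log2 change with amanitin of the genes of each of the 23 lists in BBB and BCB embryos (points, horizontal axis in log2 units), from the values as deposited. The lists for nucleolar and cytosolic ribosomal proteins lie below −2, and the oocyte list is at 0.75 in BBB. Scaled to the poly-A controls, the median of the oocyte list in BBB was −1.01.

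The other 10 lists did not pass camera's test in BBB embryos, nor in BCB embryos, where the lowest adjusted p was 0.0871. Alternatives called some of them as lower. Cholesterol and fatty acid synthesis passed with quantile normalization in BBB (0.0445), with no filter in both kinds (0.0481), with the hybridization controls (0.0164 in BBB and 0.0102 in BCB) and with the poly-A controls (0.00327 and 0.00344). The p53 targets passed with quantile normalization (0.0244 and 0.0465), the hybridization controls (0.0324 and 0.0418) and the poly-A controls (0.0134 and 0.0223). Chromatin modifiers (0.0366 and 0.02) and, in BBB, glycolysis (0.0356) passed with the poly-A controls. Fry called 8 of the 10 lists in each kind, 7 as lower and the imprinted genes as higher (0.024 in BBB and 0.000297 in BCB). For DNA methylation and chromatin modifiers 29 of 69 genes rose and 27 fell in BBB. Kdm5b, a histone demethylase, fell from 3486 ± 67.4 to 156 ± 31.7 (−4.36; −4.62 in BCB), and Trim28, a corepressor, also fell (−2.93). Dnmt3l, a cofactor of DNA methylation, rose by 1.88, and Tet3, a 5-methylcytosine dioxygenase, by 1.90, and neither passed with the poly-A controls (adjusted p 0.719 and 0.345). Dnmt1, the maintenance DNA methyltransferase, rose by 0.33 in BBB and 0.53 in BCB. In BBB its call ended without BBB array 4 or BBB_amanitin array 4 (highest adjusted p 0.0924). It was at −0.20 and −0.26 with the hybridization controls and at −1.47 and −1.29 with the poly-A controls. Among imprinted genes 20 of 52 rose and 14 fell, with Gnas, the stimulatory G protein subunit, at 2.01 (not past the test with the poly-A controls, 0.46) and Xist, the RNA of X inactivation, at −1.75 in BBB and −1.38 in BCB. The glucose transporter Slc2a3 fell by 4.24 and Slc2a1 rose by 1.246 (−0.55 with the poly-A controls), within a glycolysis list where 9 of 26 rose and 13 fell. Trim28, Dnmt3l, Tet3, Gnas, Slc2a3 and Slc2a1 were named after their values were seen.

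Cholesterol and fatty acid synthesis had 9 rises and 16 falls of 29, p53 targets and apoptosis 10 and 23 of 42, antigen presentation 6 and 7 of 18, interferon response 9 and 11 of 32 and DNA repair 17 and 16 of 42 in BBB embryos. Trim25, of the interferon list, fell by 5.53 in BCB. Of the lists for other cell types, cumulus and granulosa cell markers had 6 rises and 3 falls of 14. The 3 that fell were Amhr2, a receptor for anti-Müllerian hormone (from 2086 ± 211 to 58.9 ± 17.3, −4.84), the gap junction protein Gja1 (−4.38) and Sparc (−0.91). Sperm-carried transcripts had 4 rises (Odf2 1.08, Acrv1 0.99, Prm2 0.84 and Spata3 0.71) and 4 falls (Ldhc −1.75, Tekt2 −1.65, Tssk6 −1.41 and Pgk2 −1.30) of 16. The rises were at −0.77, −0.13, −0.19 and −0.63 scaled to the poly-A controls, and the call of Spata3 ended without BBB array 1 or BBB_amanitin array 2 (highest adjusted p 0.146). Adjusted over the list alone, the BBB counts that differed were 30 higher and 28 lower for chromatin, 10 and 24 for p53 targets and 5 and 3 for cumulus markers.

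The sign of the median, the mean and camera's test differed in some of these lists. In BBB embryos the medians of the chromatin (0.08), interferon (0.01) and DNA repair (0.02) lists were above 0, while their means (−0.40, −0.34 and −0.17) and the tests pointed down. The imprinted, cumulus and sperm lists had medians of 0.27, 0.26 and 0.12, means of −0.01, −0.36 and −0.09, and tests that pointed up. In BCB embryos the chromatin, antigen presentation, interferon and DNA repair lists had medians above 0 (0.07, 0.08, 0.08 and 0.05), with means below 0 and tests pointing down, and the cumulus list had a median of 0.31, a mean of −0.26 and a test pointing up. The imprinted list's median in BBB turned to −0.08 with the hybridization controls and −0.98 with the poly-A controls, and that of glycolysis from −0.18 to 0.12 with arrays centred on their medians. Gja1, Sparc and the 8 sperm-carried transcripts were named after their values were seen.

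The amanitin effects of both kinds of embryo were compared gene by gene, on arrays that they do not share. Timd2, Calcoco2, Rrs1 and Ctsc were among the 4563 genes that fell in both, where 1616 would overlap in independent lists, and Dph6, Mid1 and Lef1 were among the 5137 that rose in both, against 2262 in independent lists. In all, 9700 genes passed in the same direction and 10 in opposite directions. The test was passed in BBB alone by 1015 genes and in BCB alone by 1253, which does not show a difference between the kinds. The log2 changes had a Pearson correlation of 0.977 and a slope of 0.974 across genes, which are not independent replicates. A minimum change of 2-fold left 5096 shared genes.

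**Figure D3:**
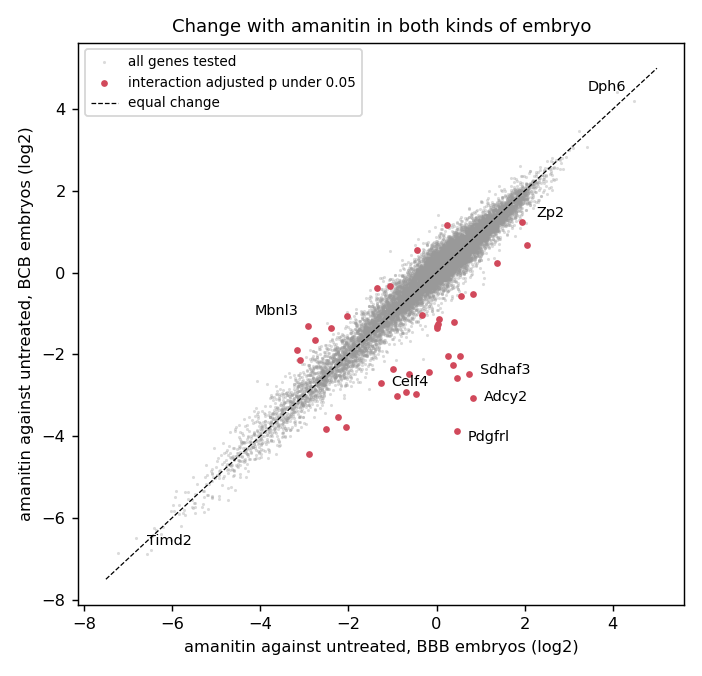
Log2 change with amanitin of each of the 15257 genes tested in BBB embryos (horizontal axis) and BCB embryos (vertical axis). Red points are the 39 genes whose change differed between the kinds at an adjusted p under 0.05, and the correlation across genes was 0.977.

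Untreated BCB and BBB embryos were compared to ask for an effect of the strain of the maternal pronucleus. Adcy2, an adenylyl cyclase, had an intensity of 20.6 ± 4.1 (SD, n = 4) in BBB and 793 ± 147 in BCB embryos, a log2 difference of 4.46 with an adjusted p of 1.66e-15. Pdgfrl, a protein related to the platelet-derived growth factor receptor, went from 3.8 ± 3.1 to 398 ± 102 (4.36, or 6.64 with a pseudocount of 1 and 2.74 with 64), the RNA-binding protein Celf4 from 22.9 ± 7.1 to 461 ± 84.7 (3.62) and Sdhaf3, an assembly factor of succinate dehydrogenase, from 22.2 ± 4.6 to 453 ± 85.3 (3.61). Mgll, which hydrolyses monoacylglycerols, went from 43.5 ± 8.4 to 335 ± 92.8 (2.52). Lower in BCB were the class I histocompatibility genes H2-K1, from 1149 ± 134 to 506 ± 86.0 (−1.16), and H2-Q5, from 429.6 ± 18.4 in BBB to 122 ± 59.3 (−1.78), and Mbnl3, a splicing regulator, from 601 ± 73.2 to 200.5 ± 64.4 (−1.55).

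Fam124a (3.09), Cfap52 (2.91), Tmed11 (2.80), F8, the coagulation factor VIII (2.66), Ajap1 (2.56), Frrs1 (2.37), Mdga2 (2.36) and the lipid droplet protein Plin2 (0.86) were also higher in BCB embryos. Kif11, a kinesin of the mitotic spindle, was higher by 0.68 (adjusted p 0.0401) and was the 1 called member of the cell cycle list. Cypt3 (−1.13), Helz2 (−1.12), Apoc2 (−1.06), Calml4 (−1.02), the iron exporter Slc40a1 (−0.96), Ciita, the activator of class II histocompatibility genes (−0.84), and the actin-binding thymosins Tmsb4x (−0.69) and Tmsb10 (−0.50) were lower. None of the 23 lists passed camera's test in this comparison. Cytosolic ribosomal proteins (median 0.07, adjusted p 0.0569, and 0.864 with an estimated correlation) passed as higher in BCB with arrays centred on their medians (0.0336), no filter (0.0481), the replicate block (0.0389) and the hybridization controls (0.0053). With the hybridization controls the spliceosome (0.0168), RNA polymerase II (0.0197), nucleolar (0.0271) and chromatin (0.0494) lists passed as well. H2-K1 was the 1 called member of the antigen presentation list. Adjusted over the list alone, the class II genes H2-Aa (0.75) and H2-Ab1 (0.82), the histone chaperone Supt16 (0.54), Mrpl27 (0.85), Mrpl35 (−0.58) and the anti-apoptotic Mcl1 (0.46) also passed, and none of these 6 did over all genes. Mgll, Ajap1, Frrs1, Mdga2, Plin2, Ciita, Tmsb4x, Tmsb10, H2-Ab1, Supt16, Mrpl27, Mrpl35 and Mcl1 were named after their values were seen.

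In the limma test 100 genes passed, 59 higher and 41 lower in BCB embryos, 39 and 7 of them at least 2-fold, and 1078 had an unadjusted p under 0.05. The balance of directions depended on the setting, with 87 higher and 20 lower scaled to the hybridization controls (where 18 of the 41 lower genes stayed), 62 and 99 scaled to the poly-A controls, 99 and 110 with a pseudocount of 64, 98 and 113 with only these 2 groups and 118 and 123 with array weights. The count was 66 without BBB array 4, and 45 without BBB arrays 3 and 4, which lie nearest to the treated arrays. It was 49 with a pseudocount of 1, 209 with 64, 161 scaled to the poly-A controls, 211 with only these 2 groups in the fit and 241 with array weights. The call of H2-Q5 ended with a pseudocount of 1 and with the mean of its probe sets (highest adjusted p 0.284), those of Helz2 (0.0733), H2-K1 and Apoc2 with a pseudocount of 1, and those of H2-K1 (0.134) and Apoc2 (0.0914) also without both BBB arrays. The call of Kif11 ended without BBB array 1, 3 or 4 or BCB array 1, 2 or 3 (highest adjusted p 0.207), that of Ciita without BBB array 4 or BCB array 3 (0.053), that of Tmsb10 without BBB array 1 or 4 or BCB array 1, 2 or 3 (0.0718) and that of Tmsb4x without BBB array 1, 3 or 4 or BCB array 1 or 2 (0.0992). All 4 calls also ended without both BBB arrays. Those of Kif11 (highest adjusted p 0.753) and Ciita (0.668) ended with a pseudocount of 1 and the mean of probe sets too, and that of Kif11 with no filter and with the poly-A controls. That of Tmsb10 (0.929) ended with both controls and the mean of probe sets, and that of Tmsb4x (0.338) with the hybridization controls. In simulated data of this size, 74% of changes of 1 on the log2 scale and all of those of 2 were found. Changes were added there at any intensity and with independent noise, so these shares may be too high for the real arrays.

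**Figure D4:**
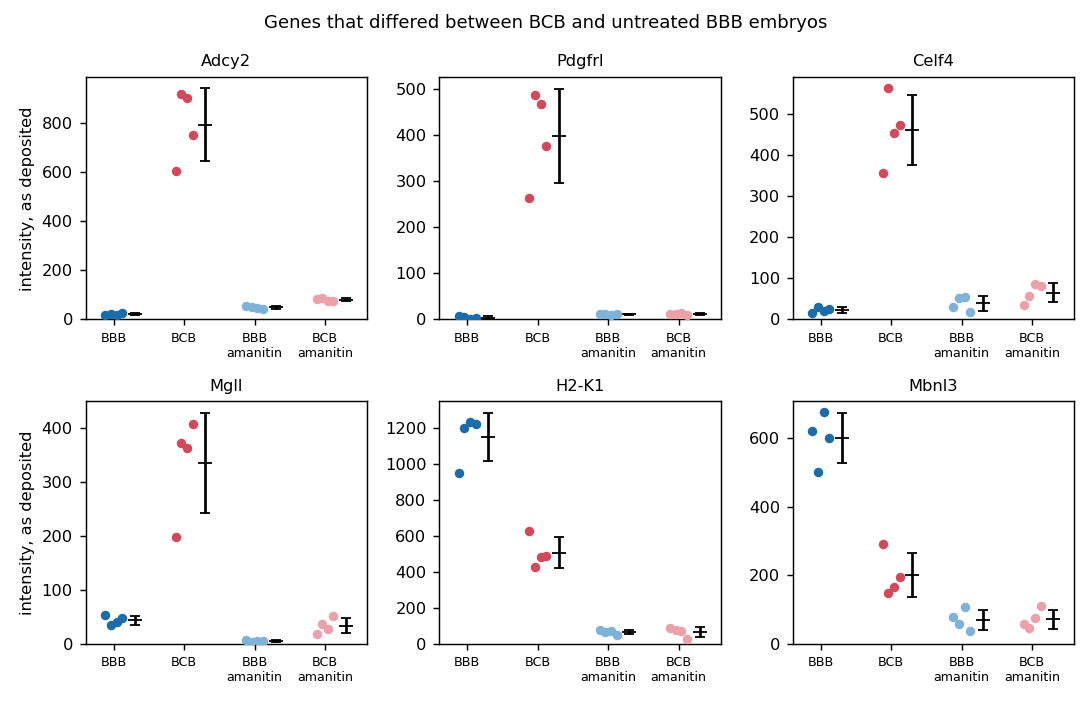
Intensity, as deposited, of Adcy2, Pdgfrl, Celf4, Mgll, H2-K1 and Mbnl3 on each array (dots) in the 4 groups, with the group mean ± SD (bars). Adcy2 was at 793 in untreated BCB against 20.6 in untreated BBB embryos, and at 80.1 against 48.5 with amanitin.

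Amanitin lowered some of the genes that differed between untreated embryos. Of the 59 genes higher in BCB, such as Adcy2 and Mgll, 27 fell with amanitin in BBB embryos, and of the 41 lower genes, such as H2-K1, 32 fell in BCB. In each case the fall is taken from the kind with the lower untreated values, so that noise in those values does not favour a fall. Of all 15257 genes, 5058 fell in BBB and 4873 in BCB, and 11 of the 59 higher genes rose in BBB. The genes were not matched to others by intensity, and a gene of low untreated intensity can hardly fall. The choice of genes may therefore still favour falls. To avoid shared BBB arrays, classes of genes were taken from BBB arrays 1 and 2 and the difference between kinds from arrays 3 and 4, and then the other way round. In the first split 49 of 4749 lowered genes differed between kinds (34 higher and 15 lower in BCB, 1.03%), against 0.23% of 5268 raised and 0.36% of 5240 unchanged ones (Fisher's exact p 3.28e-08, two-sided). In the second split the shares were 0.43% of 4631, 0.23% of 4886 and 0.24% of 5740, and the test was not passed (0.0502). The excess among lowered genes thus passed in 1 of the 2 splits. Untreated intensities of the classes were not compared, so easier calls in brighter genes stay open as its cause. That split takes the difference from BBB arrays 3 and 4, the untreated arrays of BBB nearest to the treated ones, and the median log2 difference turned between the splits, from 0.05 to −0.06 for lowered and from −0.08 to 0.07 for raised genes.

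With amanitin, BCB and BBB embryos were compared to ask for differences when the embryo does not transcribe. Rmi1, of the complex that dissolves DNA recombination intermediates, had an intensity of 717 ± 38.0 (SD, n = 4) in BBB and 1283 ± 307 in BCB embryos (0.79), and Mgll 4.6 ± 1.6 and 33.0 ± 13.8 (1.21). Mrfap1 went from 1318 ± 131 in BBB to 809.7 ± 153 in BCB (−0.71) and Fbxo15, a target of Pou5f1, from 412 ± 53 to 286 ± 27.3 (−0.50). Adcy2 was at 48.5 ± 4.2 and 80.1 ± 7.2 and did not pass (0.58, adjusted p 0.123). Also past the test were Cfap52 (1.04), Foxh1, a transcription factor of Nodal signalling (0.93), Zc3h4 (0.54), Kif27 (−1.06), Arhgap8 (−0.96), Limch1 (−0.79) and Snhg10 (−0.60). The size of differences between low intensities depends on the setting, from 0.39 to 2.76 over the alternatives for Cfap52, 0.18 to 1.94 for Foxh1, 0.49 to 1.37 for Mgll and −0.97 to −0.21 for Limch1. Mgll and Cfap52 were also higher and Limch1 and Arhgap8 also lower in untreated BCB embryos. Independent lists would share 0.02 genes in each direction (Fisher's exact p 8.26e-07, two-sided, direction not used). However, both contrasts use the same estimate of the spread of each probe set, and genes are not independent replicates. The lists are therefore not independent, and this p may overstate the overlap. Arhgap8 was named after its values were seen.

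In all, 12 genes passed in the limma test, 6 in each direction, and 1630 had an unadjusted p under 0.05. No gene passed scaled to the hybridization or to the poly-A controls, nor with only these 2 groups in the fit, where spread is estimated from fewer arrays. The count was 5, 4, 6 and 4 without BBB array 1, 2, 3 and 4, 4 and 4 without BCB array 2 and 3, 27 without BBB_amanitin array 3, 6 without BCB_amanitin array 1 and 44 without BCB_amanitin array 4. Mgll, Rmi1 and Mrfap1 kept their call in each of the 16 refits that leave out 1 array, but that of Mgll ended with a pseudocount of 1 or 64 and those of Mgll and Rmi1 with the mean of probe sets, and none of the 11 named genes kept its call under every alternative. Of the other 8 named genes, each lost its call in at least 9 of the refits, with highest adjusted p of 0.116 for Cfap52, 0.112 for Foxh1, 0.103 for Zc3h4, 0.0906 for Kif27, 0.13 for Arhgap8, 0.0997 for Limch1, 0.0928 for Snhg10 and 0.0997 for Fbxo15, and leaving out any 1 of the 16 arrays ended the call of at least 1 of them. The oocyte list was lower in BCB by a median of −0.06 (adjusted p 0.00179, against adjusted p = 0.606 with an estimated correlation), a call that quantile normalization ended (0.0949). The cell cycle list was lower by −0.06 (0.00357, and adjusted p = 0.0408 with an estimated correlation). Alternatives also called as lower the cytosolic ribosomal proteins with arrays centred on their medians (0.0342), the mean of probe sets (0.0437), the hybridization controls (0.0121) and the poly-A controls (0.0313), the proteasome with both controls (0.0324 and 0.0348) and the chaperones with the hybridization controls (0.0469).

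No member of any list passed over all genes with amanitin. Adjusted over the list alone, 11 members passed: the kinase Ttk (−0.53), Dhx15 (−0.44), Psma3 (−0.40), the Hsp40 proteins Dnajb9 (−0.68), Dnajb11 (−0.76) and Dnajb6 (−0.27), Cct3 (0.72), the fatty acid synthase Fasn (−0.60), Ehmt2 (−0.74), Parp12 (0.26) and Adar (0.40). Apart from Ttk, these were named after their values were seen.

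The interaction asks whether the amanitin effect itself differs between the kinds. Pdgfrl went from 398 ± 102 (SD, n = 4) to 11.8 ± 2.3 with amanitin in BCB embryos and from 3.8 ± 3.1 to 11 ± 0.8 in BBB, a difference of the log2 changes of −4.33. All but the untreated BCB values of Pdgfrl are low, so the size of its difference depends on the pseudocount, with −6.57 at 1 and −2.73 at 64, as it does for Mdga2 below (−5.27 and −1.23). Adcy2 (−3.88), Sdhaf3 (−3.23), Celf4 (−3.04), Mdga2 (−2.64), F8 (−2.56), Fam124a (−2.51) and Tmed11 (−2.29), each higher in untreated BCB than BBB embryos, also had a lower log2 change in BCB. In the other direction, Mbnl3 fell from 601 ± 73.2 to 69.8 ± 30 in BBB and from 200.5 ± 64.4 to 71.8 ± 28.2 in BCB (1.60). Flvcr1, a heme exporter (1.27), Pcdh8 (1.09), Parp8 (1.04), Cypt3 (1.01), Slc40a1 (0.99), the purine receptor P2ry1 (0.99) and Rmi1 (0.95) had a higher log2 change in BCB.

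The limma test called 39 genes, 10 with a positive and 29 with a negative interaction, 5 and 27 of them at least 2-fold, and 1230 had an unadjusted p under 0.05. Few positive calls were left with arrays centred on their medians (1, beside 34 negative), the hybridization controls (2 and 48), quantile normalization (3 and 25), no intensity trend (3 and 26), no filter (4 and 22) or a pseudocount of 1 (1 and 14), while a pseudocount of 64 gave 17 and 41. Of the 59 genes higher in untreated BCB embryos, 28 were called here, on the same untreated arrays. The count was 15 with a pseudocount of 1, 22 and 24 without BBB array 3 and 4, and 20, 23 and 23 without BCB array 2, 3 and 4. The 8 genes named with a negative interaction kept their call in each of the 16 refits that leave out 1 array, though that of Fam124a ended with a pseudocount of 1 (0.0589). Those with a positive one lost it in at least 8 of the refits, with highest adjusted p of 0.107 for Mbnl3, 0.117 for Flvcr1, 0.142 for Pcdh8, 0.0893 for Parp8, 0.123 for Cypt3, 0.14 for Slc40a1, 0.132 for P2ry1 and 0.0745 for Rmi1, and leaving out any 1 of the 16 arrays ended at least 1 of these calls. Flvcr1 turned to −0.16 scaled to the hybridization controls. Cytosolic ribosomal proteins had a median interaction of −0.14 (adjusted p 0.00423, against adjusted p = 0.686 with an estimated correlation). Cell cycle genes had −0.07 (0.0103, against adjusted p = 0.0518 with an estimated correlation), which quantile normalization ended (0.0949). With the hybridization controls the oocyte (7.38e-05), chromatin (0.0276), nucleolar (0.0312) and spliceosome (0.0462) lists were called as lower, the oocyte list also with arrays centred on their medians (0.016) and the mean of probe sets (0.0378), and fry called glycolysis as higher (0.0233). No member of any list passed over all genes, and adjusted over the list alone Tpi1 (0.80), H2-K1 (1.12) and H2-Ab1 (−1.24), named after their values were seen, did.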

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

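Of the tests in this part, those of a sequence variant in the higher genes and in genes with no other bright probe set, of carried-over ooplasm, of array scaling and of less mRNA were chosen after their results were seen, and the drift test after seeing the data but before its result.

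For 20 named genes the amanitin effect differed between the kinds of embryo by the interaction test, as the difference of log2 changes, BCB minus BBB. It was negative for Pdgfrl (−4.33), Adcy2 (−3.88), Sdhaf3 (−3.23), Celf4 (−3.04), Mdga2 (−2.64), F8 (−2.56), Fam124a (−2.51), Tmed11 (−2.29), Ajap1 (−2.27), Frrs1 (−2.13), Cfap52 (−1.87) and Mrfap1 (−0.72). It was positive for Mbnl3 (1.60), Flvcr1 (1.27), Pcdh8 (1.09), Parp8 (1.04), Cypt3 (1.01), Slc40a1 (0.99), P2ry1 (0.99) and Rmi1 (0.95). The lists of cytosolic ribosomal proteins (−0.14) and of the cell cycle (−0.068) also differed in camera's test, which neither did with an estimated correlation.

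Most of the genes with a negative interaction, among them Adcy2, Pdgfrl and Celf4, were higher in untreated BCB than in BBB embryos. A sequence variant under the probes is argued against for the genes with another bright probe set as a set, not for each gene. The other probe sets had a median difference of 0.64 for 12 of the higher genes (11 in the same direction, exact sign test p 0.00635). It was −0.63 for 11 of the lower genes (10 in the same direction, 0.0117). A variant stays open for single genes. The other probe set was at 0.21 against −0.695 for Limch1 and at 0.18 against 1.07 for Zfp618, named after its values were seen. Those of H2-K1 were at −0.88 and −0.33 against −1.16. For the 47 of 59 higher and 30 of 41 lower genes with no other bright probe set, a variant cannot be told apart from a change in the transcript. C3H ooplasm carried over with the pronucleus was tested only as a source of transcripts. As such it is argued against for the higher genes as a set by a median of 0.11 with amanitin, against 1.18 untreated, though 40 of 59 kept the sign. For the 2 that were still called with amanitin, Mgll (1.21 of 2.52) and Cfap52 (1.04 of 2.91), carried-over transcripts cannot be told apart from other causes. An effect of carried-over ooplasm on transcription by the embryo would also be lost with amanitin, so it stays open. Drift of the arrays along the axis from untreated to treated was not decided. All 100 of 100 called genes kept their call with that position as a term. However, the positions of the BBB arrays (−0.54 to −0.45) spanned those of BCB (−0.52 to −0.48), so the term could hardly move a difference between the kinds. Without BBB arrays 3 and 4, which lie nearest the treated arrays, 42 kept their call and all 100 their direction (median size 0.86 against 0.95). Transcription from the C3H maternal genome in the embryo may account for most of the higher genes, and stays open as a hypothesis found on these data, as do untested effects of the making of the embryos.

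Control probe sets, outside the comparisons of genes, were higher on the treated arrays: the hybridization controls by 0.56 in BBB and 0.81 in BCB embryos, the poly-A controls by 1.86 and 1.88, and 18S ribosomal RNA by 1.26 and 1.63 on the log2 scale. The scaling of each array alone, judged by the hybridization controls, is argued against as the whole cause of the rises in BBB embryos. With it 56.54% of the 5667 genes stayed higher. In BCB embryos 37.62% of 6090 stayed higher, which goes the same way for those genes, and 367 turned lower. For the rises that did not stay, in both kinds, it cannot be told apart from other causes. Less embryo mRNA in the treated samples, with each array scaled to one trimmed mean, may account for most of the rises. Scaled to the poly-A controls, 2.72% in BBB and 2.07% in BCB stayed higher. This holds if these controls were added in equal amounts to each sample, which the sources used here do not say. Slower loss of maternal transcripts in embryos that do not transcribe stays open and was not tested.

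Single arrays stood apart from the other 3 of their group in 36 of 592 groups of a gene and in 1 of 32 groups of an array measure, and chance flags about 1 in 20 groups. The values that follow are the gap to the nearest array divided by the range of the group. In BBB embryos array 1 was high for Cypt3 (0.903) and low for H2-K1 (0.899) and Spata3 (0.835), and array 2 was high for Mcl1 (0.911). In BCB embryos array 1 was high for Apoc2 (0.899) and low for Fam124a (0.865), Mgll (0.834) and Supt16 (0.89), and array 4 was high for Lef1 (0.934) and Oas1f (0.861) and low for Timd2 (0.935). In BBB embryos with amanitin array 1 was low for Casp8 (0.928) and high for Rrs1 (0.848), and array 2 was high for Btbd18 (0.888) and Odf2 (0.834) and low for Mos (0.962) and Ubtfl1 (0.897). There array 3 was low for Ajap1 (0.894) and Snhg10 (0.869), and array 4 for Cdk9 (0.861), Ctsc (0.837) and Oas1f (0.859). In BCB embryos with amanitin array 1 was high for Mycl (0.916), Nip7 (0.832) and Psme3 (0.855) and low for Dhx15 (0.848) and Tmsb4x (0.847), and array 2 was high for Cdc25b (0.904) and Ldhc (0.872) and low for Mrpl35 (0.874) and Pramel7 (0.948). There array 3 was high for Tmed11 (0.948), and array 4 was high for Frrs1 (0.881), Pgk2 (0.873) and Tet3 (0.871) and low for Cyp2f2 (0.915). The 75th percentile of array 1 of that group was high (0.833).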

How the results depend on the processing

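Scaling to the hybridization or poly-A controls, the axis position as a term and leaving out BBB arrays 3 and 4 were chosen after seeing the data; the other alternatives were fixed before. The alternative for values near a floor was not run, since the values are linear. With no filter on low probe sets 326 results kept direction and side of the threshold, with a filter at the 60th percentile 339, with quantile normalization 319 and scaled to the poly-A controls 278. The number of lowered genes that differed between kinds, averaged over both splits, ranged from 28 to 40.5 over the alternatives run, against 34.5. Low signals limit the size of some changes, such as the interaction of Pdgfrl, at −6.57 with a pseudocount of 1 and −2.73 with 64. For the values below that moved or turned, the cause was not tested, except that a 2-fold minimum leaves fewer calls by construction.

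BCB against BBB untreated called 49 genes with a pseudocount of 1, 209 with 64, 161 scaled to the poly-A controls, 211 with only the 2 groups, 241 with array weights, 46 with a 2-fold minimum, 340 with the axis position and 45 without BBB arrays 3 and 4. With amanitin the same contrast called 0 genes scaled to the hybridization controls, 0 to the poly-A controls and 0 with only the 2 groups, 4 with the mean of probe sets, 6 with the replicate block, 2 with no intensity trend, 1 with array weights and 4 with a 2-fold minimum. The interaction called 15 with a pseudocount of 1. A 2-fold minimum left 5771 genes with amanitin in BBB, 5684 in BCB and 5096 shared. An estimated correlation left 5 of 30 list calls. Leaving out 1 array gave 10212 to 10781 genes with amanitin in BBB, 10439 to 11044 in BCB, 9389 to 9624 shared, 66 (without BBB array 4) to 108 between untreated kinds, 4 to 44 (without BCB_amanitin array 4) with amanitin and 20 (without BCB array 2) to 43 for the interaction.

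Log2 changes with amanitin in BBB embryos turned scaled to the poly-A controls for Zp3 (−1.80), Gdf9 (−1.09), Mos (−0.19), Dnmt1 (−1.47), Bmp15 (−0.40), Nlrp5 (−0.42), Pou5f1 (−0.59), Btg4 (−0.81), Yap1 (−1.24), Rps2 (−1.72), Rpl39 (−1.52), Rps27l (−1.64), Slc2a1 (−0.55), Psme3 (−0.012), Cdc25b (−0.016), Duxf3 (−0.22), Gata3 (−0.24), Klf17 (−1.58), Mycl (−0.23), Nvl (−0.47), Pes1 (−1.46), Odf2 (−0.77), Acrv1 (−0.13), Prm2 (−0.19) and Spata3 (−0.63), and in BCB for Gdf9 (−1.25), Mos (−0.25), Dnmt1 (−1.29), Rps2 (−1.60) and Rpl39 (−1.19). Scaled to the hybridization controls those of Zp3 (−0.52), Dnmt1 (−0.20), Rps2 (−0.42), Rpl39 (−0.39), Rps27l (−0.34), Klf17 (−0.28) and Pes1 (−0.19) turned in BBB, those of Gdf9 (−0.19), Dnmt1 (−0.26), Rps2 (−0.54) and Rpl39 (−0.29) in BCB, and the interaction of Flvcr1 (−0.16). Quantile normalization turned Yap1 (−0.008), Rps2 (−0.44), Rps27l (−0.29) and Klf17 (−0.31) in BBB and Rps2 (−0.27) in BCB, and the mean of probe sets turned Pes1 (−0.083). For the cumulus list fry pointed down, against camera's up, with adjusted p of 0.000201 in BBB and 0.00197 in BCB.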

Other observations

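Of the tests in this part, the noise test of single probe sets, the test of shared probe sets and the other splits for the kinds with amanitin and for the interaction were chosen before their results were seen; the other splits, the neighbour test, the family tests and the test of transcript forms were chosen after.

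Gene families defined by the start of the symbol were counted for falls of at least 2-fold with amanitin. Among 63 families of at least 20 genes (252 tests), RNA helicases named Ddx fell in 22 of 35 genes in BBB embryos (62.9%, against 21.8% of other genes, Fisher's exact adjusted p 1.29e-05) and in 22 in BCB (8.63e-06). RNA polymerase subunits named Polr fell in 16 of 25 in BBB (0.00022) and 17 in BCB (2.91e-05), with family medians of −1.67 and −1.85. Both families passed in both kinds under each of the 4 scalings run (highest adjusted p 0.000102 for Ddx and 0.0165 for Polr). General transcription factors named Gtf fell in 11 of 22 in BBB (0.0418) and 12 in BCB (0.0119), RNA-binding proteins named Rbm in 15 of 32 (0.0291) and 16 (0.0068), and zinc finger genes named Zfp in 90 of 303 (29.7% against 21.7% of other genes, 0.022) and 85 (0.0418). Scaled to the hybridization controls these calls ended for Gtf in BBB (0.104) and BCB (0.0756), for Rbm in BBB (0.0528) and for Zfp in BBB (0.0972), and further calls ended for Gtf in BCB with the poly-A controls (0.0975) and for Rbm in BBB with arrays centred on their medians (0.0518).

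Rab GTPases rose at least 2-fold in 21 of 71 in BBB (29.6% against 15.9%, 0.0418; 0.117 in BCB) and the myosins named Myo in 9 of 21 in BCB (0.0418; 0.22 in BBB), and both calls ended under each of the 4 scalings, while Myo in BBB passed scaled to the hybridization controls (6 of 21, 28.6% against 5.7%, 0.013). Fewer keratins named Krt fell than other genes, with 1 of 35 in BBB (0.0418; 0.0521 in BCB), and fewer genes named Lrrc, with 1 of 40 in BCB (0.0248; 0.0583 in BBB). The call of Krt ended with quantile normalization (0.0769) and arrays centred on their medians (0.102), and that of Lrrc with arrays centred on their medians (0.0603) and the poly-A controls (0.929). With quantile normalization Lrrc genes passed as raised at least 2-fold in 16 of 40 in BBB (0.027) and in BCB (0.0248), which they did not under the other 3 scalings. Interleukins and their receptors named Il fell in 2 of 54 in BCB (0.0119; 0.0604 in BBB), a share below that of other genes that passed in BCB under each of the 4 scalings. Scaled to the hybridization and poly-A controls the low shares also passed for Krt in BCB (0.00754 and 0.000177) and Il in BBB (0.0122 and 1.84e-06), and with quantile normalization for Lrrc in BBB (0.0441). With a pseudocount of 16, a gene at an intensity under 16 cannot fall 2-fold. The intensities of these families were not compared with those of other genes, so a low share of falls does not show a lack of response to amanitin. The families named Eif, Rpl and Rps, covered by lists above, passed with falls in both kinds and under each of the 4 scalings. Some members of Ddx, Polr, Gtf and Rbm are also in the nucleolar, spliceosome or RNA polymerase II lists. Their family tests are thus not separate from the list tests. Differences of the families between the kinds were not tested, and all families were chosen after the data were seen.

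In 839 of the 6809 genes with several probe sets, probe sets of the same gene moved in opposite directions with amanitin in BBB embryos. In Med14, a subunit of Mediator, one probe set rose by 1.66 and another was at −3.77, and Rnf24 had 2.06 and −2.14 and Ube2a, a ubiquitin-conjugating enzyme, 1.78 and −2.20, all 3 named after their values were seen. Opposite directions are relative to the scale of each array, since scaled to the poly-A controls 13 of the 839 genes remained both ways, Rnf24 among them but neither Med14 nor Ube2a. Noise of single probe sets is argued against by 72.5% of the genes (608) splitting the same way in BCB embryos, and probe sets shared by several transcripts by 71% (596) staying with the other probe sets alone. Of the 116 genes with 2-fold changes both ways, 5 were still called both ways scaled to the poly-A controls. Transcript forms with different ends in the oocyte and the embryo may account for some of the 116 genes. This cannot be told apart from other causes, since no probe position was used. Between the untreated kinds, 2 genes had probe sets called in opposite directions, with no minimum change.

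Genes called between untreated BCB and BBB embryos may lie near each other more often than random genes. There were 8 pairs within 5 places in gene order, such as Ccdc126 (1.48) with Fam221a (2.50) and Slc10a6 (−0.62) with Nudt9 (−0.65), against a median of 3 and a 95th percentile of 6 in 10000 random sets (permutation p 0.0172), and 5 of the 8 pairs had the same direction. The other 3 pairs, such as Nfkbil1 (1.13) with H2-Q5 (−1.78), had opposite directions, so a change shared by neighbouring genes is not shown, and no region is named. The genes of these pairs, apart from H2-Q5, were named after their values were seen.

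Other splits of the same 8 arrays were counted beside the real one. For amanitin in BBB embryos only the real split of 35 gave as many genes (1 of 35), with 10725 genes against at most 0 in the others. The same held in BCB (1 of 35, 10963 against 0). Every other split mixes treated and untreated arrays, which puts the treatment effect into the spread, so the counts of 0 add little. For untreated BCB against BBB only the real split gave as many (1 of 35, 100 genes against at most 22). For the interaction 1 of 100 draws did, the real one, though the highest other draw came close (39 against 34). A share of 1 of 35 is the smallest that 35 splits allow, so chance is argued against in these comparisons but not excluded. It stays open for BCB against BBB with amanitin, where 4 of 35 splits gave as many as the real 12 genes. The highest there, 60 genes, sets BBB_amanitin arrays 1, 2 and 3 with BCB_amanitin array 4 against the other arrays. That split was singled out after the counts were seen. On principal component 2 of all arrays (1.61% of the variance), BCB_amanitin array 4 was at 14.74. The BBB_amanitin arrays were at 2.13 to 19.65, and BCB_amanitin arrays 1, 2 and 3 at −42.29, −18.91 and −13.64. Leaving out BCB_amanitin array 4 gave 44 genes. A structure of the samples other than the kind was not tested.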
